A study of Mus musculus with 8 samples.

How the data were processed

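Bulk RNA from the ventral pallidum of C57BL/6 mice was measured by RNA sequencing in 8 libraries, 4 from mice that self-administered saline and 4 from mice that self-administered cocaine. Per the labels, RNA was extracted with Trizol and a column kit with DNase treatment, libraries were made from 90 ng of RNA with the NEBNext Ultra kit, and 75 bp paired-end reads were sequenced on a HiSeq 4000. Per the submitters' processing notes, TopHat and DESeq were used with the GRCm38 build. Versions, settings, the gene annotation and the counting tool are not given in the sources used here, and neither is whether counting used strand.

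One table of the whole series was used, with 32787 genes identified by Ensembl IDs. The deposited values per library are on a log2 scale, from 4.50 to 17.1, and are called variance-stabilised here from their form, since a gene with no reads sits at the floor and not at 0. Per the file headers, the authors also gave mean read counts per group and over all libraries, which are normalized by size factors and were treated as a signal that is not negative, not as raw counts. The deposited fold change is a linear ratio of the group means, and the deposited log2 fold change is its logarithm. The deposited p-values and FDR are those of the authors' comparison, and they were copied without change. All 8 columns of per-library values were matched to libraries by their names, and 0 such columns were left unused.

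Normalized read counts were recovered from the log2 values. For a gene with reads in 1 library only, the group mean gives the normalized value of that library's reads, and these values were whole multiples of 1 step per library. The step fixed the scale of each library, and the log2 values were then inverted gene by gene with a curve fitted to these points and to the group means. For 32657 of 32787 genes (99.6%) the 2 group means computed from the recovered whole reads matched the deposited means within 0.01 normalized reads. The other 130 genes had means of at least 17366 and differed by at most 0.0419%. The recovered reads summed to 26163772 to 36171462 per library. Of the IDs, 32650 were found in the GENCODE vM21 annotation of GRCm38, from which gene coordinates and overlaps were taken.

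Genes with a mean of at least 10 normalized counts over the 8 libraries were tested, which left 18812. The design fixed before the data were examined assumed log2(value + 1) of normalized values. As the deposited values were already on a log2 scale, they were fitted as deposited, and log2 of the recovered normalized counts plus a pseudocount of 1 was added as an alternative. The test was limma 3.58.1 in R 4.3.3 with an intensity trend and robust variance prior, group as the only term, and Benjamini-Hochberg adjustment at 0.05, two-sided. A log2 difference on the variance-stabilised scale understates the change of genes with few reads. It was also smaller than the ratio of counts gives for 2 highly abundant features. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 differed by 0.06 and 0.08 at 1.08-fold and 1.12-fold of saline. Ratios are those of the mean recovered counts. No batch is named in the labels.

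There were 32 gene lists, fixed before the data were examined. They covered immediate early, circadian, glucocorticoid-responsive and heat shock genes, markers of pallidal, cholinergic, subcortical glutamate, striatal and cortical neurons, neuropeptides, markers of astrocytes, oligodendrocytes and their precursors, microglia, vessels, choroid plexus, ependyma, meninges and red blood cells, and genes of receptors, synapses, channels, axon guidance, matrix, chromatin, inflammation, respiration and ribosomes. They were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives fixed with the lists, and an exact permutation of each list's library means was added after seeing the data. A marker score per library, the mean log2 value of striatal markers minus that of pallidal markers, was also added after seeing the data.

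Named genes were fixed by rule before the data were examined. As 0 genes passed, the rule took in each direction the 10 genes with a symbol and the smallest unadjusted p whose groups did not overlap, leaving out gene models, clones and pseudogenes, of which 4 higher and 2 lower were passed over. It also took the 2 members of smallest unadjusted p in each list, and Fos, Egr1, Nr4a1, Arc, Npas4, Pvalb, Slc17a6, Gad1, Chat, Penk and Drd1. Genes of the authors' deposited table, Capn11, Rpl31, Ttr, Bhlhe41, Ifit3, Nr1d1 and the mitochondrial ribosomal RNAs were named after their values were seen. In total 89 genes came from the rule, and 32 of them overlap a gene on the other strand; 3 of the 89 are not reported here.

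Alternatives were pseudocounts of 0.5 and 5 on recovered counts, no low-value filter, a minimum mean of 50, quantile normalization, TMM factors (30% and 5% trims), each library left out, the replicate number as a block, array quality weights, and limma without trend and robust. Added after seeing the data were the pseudocount of 1, voom weights on recovered reads, the marker score as covariate, also with an estimated correlation in camera, and leaving out the 2 libraries at the ends of the score. The steps were tested on simulated data for 18834 genes with known changes in 200 genes, where limma recovered 46% of 50 genes changed by 0.5 on the log2 scale, 76% of those changed by 1, 90% by 2 and 96% by 3. Of the calls, 9 of 163 were genes without a change. The simulated genes varied independently of one another, while genes of the real libraries moved together. These rates therefore do not describe the recovery or the false calls in the real data.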

Results

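RNA sequencing was carried out on bulk ventral pallidum, a basal forebrain output structure of the reward circuit, from C57BL/6 mice. Mice self-administered cocaine at 0.5 mg per kg per infusion or saline for 10 days, and the tissue was taken 24 h after the last session. There were 4 libraries per group. The libraries held 29273552, 32890427, 32631358 and 26163772 gene-assigned reads in saline replicates 1 to 4 and 36171462, 31238892, 31269987 and 30369334 in cocaine replicates 1 to 4, as recovered from the deposited values. Values are normalized read counts given as mean ± SD with n = 4 per group. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between these libraries. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 4.76 over 14883 genes.

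The comparison asks which transcripts of the ventral pallidum differed 1 day after cocaine taking. At the level of single genes no difference exceeded the spread between libraries after adjustment for the number of genes. Among the genes with the smallest unadjusted p were Mir6236, annotated as a microRNA gene, and Rn18s-rs5, a sequence related to 18S ribosomal RNA, both at lower levels in cocaine. Mir6236 (chromosome 9, 110281287 to 110281409, GRCm38) measured 514 ± 99.1 in saline and 238 ± 29.5 in cocaine. Which transcript gave the reads at this locus was not tested, so they are not taken as the level of a mature microRNA. Rn18s-rs5 measured 25097 ± 9331 in saline and 9634 ± 1331 in cocaine. As groups, striatal neuron markers lay higher and pallidal neuron, astrocyte and myelin markers lower in the cocaine libraries by limma camera with a preset correlation. With an estimated correlation the adjusted p was 0.843 for each of these lists.

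With limma on the log2 values, 0 of 18812 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.290, for Mir6236. Voom weights on the recovered reads also gave 0 genes, as did limma without trend and robust. At an unadjusted p below 0.05 there were 2236 genes, of which 1096 were higher and 1140 lower in cocaine, where chance alone gives 940.6. This count was 1158 without saline replicate 1, 1432 without saline replicate 4, 4356 without saline replicate 3, 1075 without cocaine replicate 1 and 1083 without cocaine replicate 4. The groups did not overlap for 1186 genes, 6.30% of those tested, against 2.86% by chance. Both chance values are averages, and genes that move together spread the counts widely around them. Of 35 splits of the 8 libraries into 4 and 4, 4 gave at least 2236 genes, the real one included. An excess over these averages therefore does not show a difference between the groups.

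The genes named next had the smallest unadjusted p among genes whose groups did not overlap, and none passed the adjustment (limma, adjusted p = 0.418 for each except Mir6236). Among genes lower in cocaine, Hcn2, a pacemaker channel subunit (chromosome 10, 79716634 to 79736108), measured 5880.5 ± 301 in saline and 4583 ± 371 in cocaine, a log2 difference of -0.41 ± 0.08 (SE). Pcsk1n, which encodes the proSAAS inhibitor of a prohormone convertase (chromosome X, 7919822 to 7924410), measured 22689 ± 1269 in saline and 17411 ± 1239 in cocaine. Sema7a, a membrane-anchored semaphorin (chromosome 9, 57940112 to 57962865), measured 2979 ± 169 in saline and 2318 ± 186 in cocaine. Nrtn, a ligand of the GDNF family, was at 0.64-fold of saline, Grid2ip at 0.57-fold, the fructose-phosphorylating enzyme gene Khk at 0.74-fold and Etl4 at 0.83-fold. Among genes higher in cocaine, Spink8, a Kazal-type protease inhibitor gene (chromosome 9, 109812280 to 109826633), measured 50.5 ± 9.37 in saline and 89.7 ± 10.2 in cocaine. Dcx, a microtubule-associated protein of immature neurons (chromosome X, 143855842 to 143933311), measured 993 ± 42.9 in saline and 1158 ± 12.2 in cocaine. The retinoblastoma gene Rb1 was at 1.17-fold of saline, Rbm12b1 at 1.33-fold, Ccdc39 at 1.21-fold, the synaptic adhesion gene Lrrtm4 at 1.34-fold, Hectd2 at 1.29-fold, the phosphodiesterase gene Pde1c at 1.29-fold, Ppef2 at 1.53-fold and Zbtb40 at 1.29-fold. Pcsk1n, Etl4, Grid2ip, Rn18s-rs5, Rb1, Ccdc39, Lrrtm4, Hectd2 and Zbtb40 overlap an annotated gene on the other strand, and the labels do not say that reads were counted by strand.

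**Figure D1:**
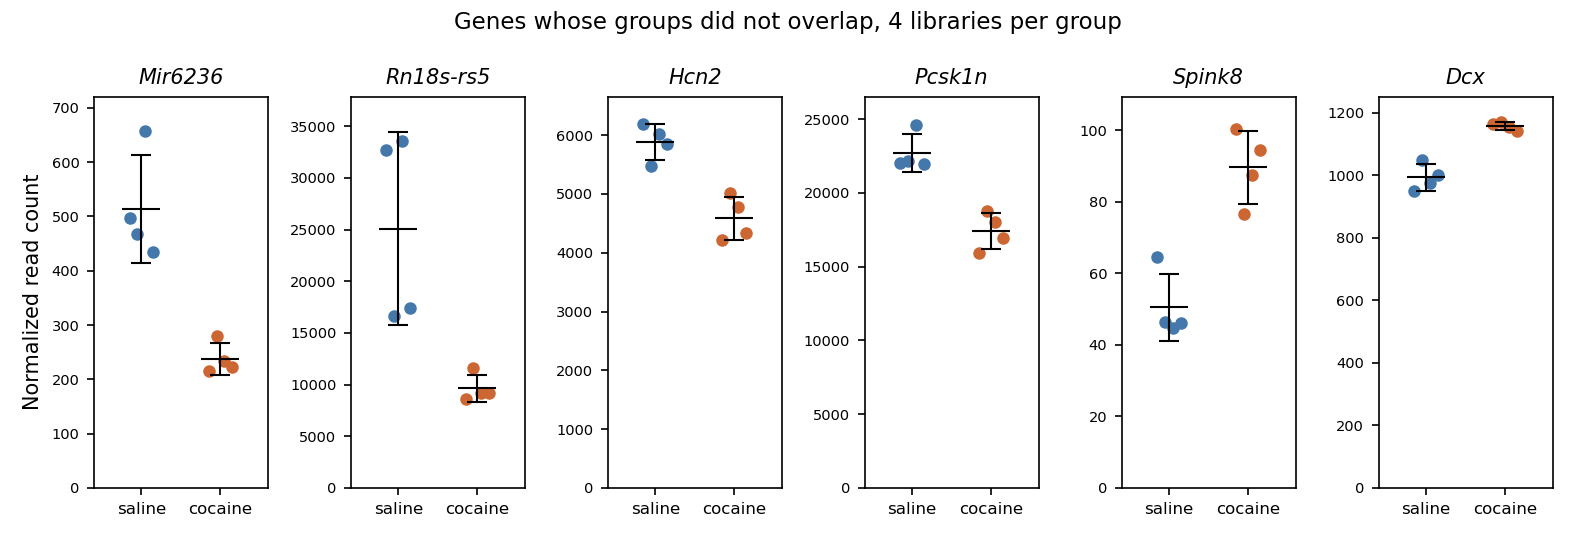
Normalized read counts of 6 genes in each library, on linear axes starting at 0, for saline (blue) and cocaine (orange); points are libraries, and the black bar and whiskers are the mean and SD of 4 libraries. For Mir6236 the saline libraries measured 434 to 658 and the cocaine libraries 215 to 281, and no gene passed the adjustment for the number of genes.

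Striatal projection neuron markers were higher in cocaine, with a median log2 difference of 0.50 over 23 measured members (limma camera with preset correlation, adjusted p = 3.06e-05; adjusted p = 0.843 with an estimated correlation). All 23 had a positive log2 difference, 0 at an unadjusted p below 0.05 and 0 when adjusted over the list alone. The dopamine receptor gene Drd1 (chromosome 13, 54051183 to 54055705) measured 3224 ± 1333 in saline and 4787 ± 1444 in cocaine, and the enkephalin precursor gene Penk (chromosome 4, 4133531 to 4138819) measured 21292 ± 8358 in saline and 30231 ± 7644 in cocaine. Arpp21 measured 24861 ± 9681 in saline and 37206 ± 10701 in cocaine and the substance P precursor gene Tac1 3077 ± 1287 in saline and 4795 ± 1452 in cocaine. Pallidal and basal forebrain GABA neuron markers were lower, with a median of -0.30 over 18 members (adjusted p = 2.49e-04 by limma camera; adjusted p = 0.843 with an estimated correlation). Of these, 16 had a negative difference, 7 at an unadjusted p below 0.05 and 0 adjusted over the list alone. Parvalbumin (Pvalb, chromosome 15, 78191114 to 78206400) measured 851 ± 139 in saline and 587 ± 139.8 in cocaine, the potassium channel gene Kcng4 111 ± 26.4 in saline and 69.9 ± 21.9 in cocaine, and the GABA-synthesizing enzyme gene Gad1 21461 ± 1377 in saline and 20216 ± 1460.0 in cocaine. The striatal median was 0.25 without saline replicate 1, 0.77 without saline replicate 3 and 0.33 without cocaine replicate 1, and the pallidal median -0.16 without cocaine replicate 1.

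The libraries of each group differed widely in these markers. The striatal mean minus the pallidal mean was 0.58, 1.71, 2.54 and 0.93 on the log2 scale in saline replicates 1 to 4 and 3.05, 1.72, 1.63 and 2.50 in cocaine replicates 1 to 4. The group means were 1.44 ± 0.87 and 2.22 ± 0.67 (SD, n = 4), a difference within the spread between libraries (exact two-sided permutation test, p = 0.257). With this marker score held constant, the striatal median was -0.06 (limma camera adjusted p = 0.366) and the pallidal median -0.01 (adjusted p = 0.405), but both lists define the score. Without the 2 libraries at the ends of the score, saline 1 and cocaine 1, the adjusted p by limma camera was 0.344 for the striatal list, with a median of 0.12, and 0.0285 for the pallidal list, with a median of -0.09.

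**Figure D2:**
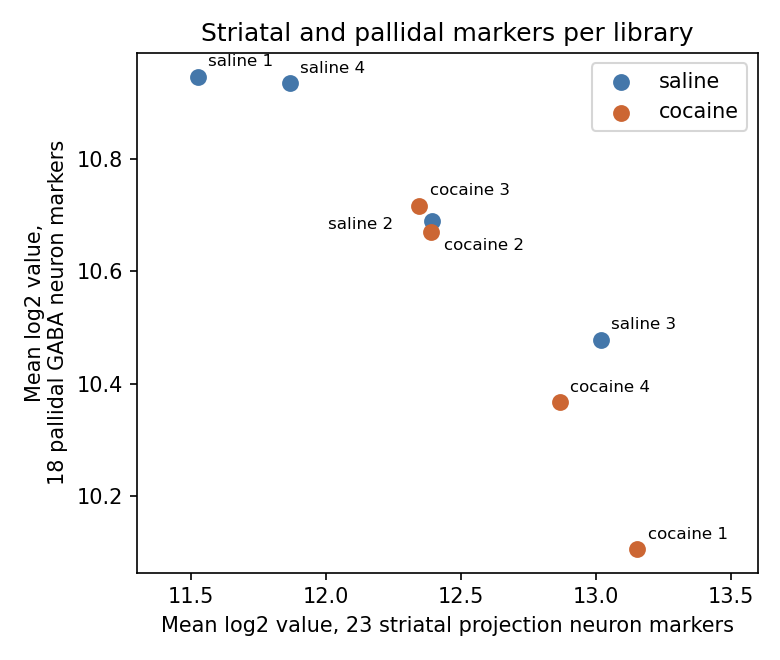
Mean log2 value of 23 striatal projection neuron markers (x axis) against that of 18 pallidal and basal forebrain GABA neuron markers (y axis); each point is 1 library, saline in blue and cocaine in orange. Saline 1 lies at the upper left and cocaine 1 at the lower right, with libraries of both groups between them.

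Among glial lists, astrocyte and myelin markers were lower in cocaine, with an adjusted p of 0.843 for both lists at an estimated correlation. Oligodendrocyte precursor markers had a median of -0.13, as large as that of myelin markers, and did not pass, and the difference between the lists was not tested. Astrocyte markers had a median log2 difference of -0.20 over 20 members, of which 17 were negative, 4 at an unadjusted p below 0.05 and 0 adjusted over the list alone (limma camera, adjusted p = 0.00216). The amino acid transporter gene Slc7a10 measured 1363 ± 237 in saline and 963 ± 189 in cocaine, and Acsbg1 measured 5834 ± 479 in saline and 4953 ± 637 in cocaine. Mature oligodendrocyte and myelin markers had a median of -0.13, with 24 of 25 members negative, 2 at an unadjusted p below 0.05 and 0 adjusted over the list alone (limma camera, adjusted p = 0.00379). Klk6, a serine protease gene, measured 221 ± 41.7 in saline and 166 ± 10.3 in cocaine. The myelin call was lost without saline replicate 1 (adjusted p = 0.0689 by limma camera) and without saline replicate 4 (0.25). The astrocyte median was -0.11 without cocaine replicate 1, and the myelin median was -0.28 without saline replicate 3, -0.05 without saline replicate 4, -0.08 without cocaine replicate 1 and -0.21 without cocaine replicate 2. With the marker score held constant, the medians were 0.000108 for astrocytes and 0.08 for myelin. Without saline 1 and cocaine 1 the adjusted p by limma camera was 0.424 for both.

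Immediate early genes, which neurons transcribe soon after activity, were higher in cocaine as a group by limma camera with the preset correlation (adjusted p = 0.0184; adjusted p = 0.843 with an estimated correlation). The median log2 difference was 0.13 and the mean 0.22 over 36 members, with 23 positive, 8 of them at an unadjusted p below 0.05 and 0 adjusted over the list alone. Klf10 measured 235 ± 17.4 in saline and 348 ± 68.1 in cocaine, and Nr4a1 measured 955 ± 162 in saline and 1337 ± 194 in cocaine. Egr1 (chromosome 18, 34859823 to 34864984) measured 2012 ± 434 in saline and 3599 ± 1418 in cocaine, a log2 difference of 0.88 ± 0.31 (SE) with overlapping groups (limma adjusted p = 0.418). Nr4a3 measured 226 ± 41.2 in saline and 608 ± 346 in cocaine, with no overlap between groups (limma adjusted p = 0.418). Fosl2 and Homer1, also on this list, were at 1.86-fold and 1.65-fold in the authors' deposited table. Of the 36 members, 13 lay lower in cocaine. Fos, Arc and Npas4 differed by less than the SD between saline libraries. Fos (chromosome 12, 85473890 to 85477273) was at 123 ± 124 in saline and 120.2 ± 23.9 in cocaine. Arc was at 847 ± 273 in saline and 889 ± 231 in cocaine, and Npas4 at 284 ± 99.1 in saline and 301 ± 51.7 in cocaine. In saline replicate 1, Fos measured 308 and the other saline libraries 54.6 to 74.4, and without it Fos was at 1.96-fold of saline. Circadian clock and output genes had a median of 0.24, with 16 of 19 positive and 7 at an unadjusted p below 0.05 (limma camera, adjusted p = 6.00e-04; adjusted p = 0.843 with an estimated correlation). Adjusted over the list alone, 3 members passed. These were the clock repressor genes Cry1 (chromosome 10, 85131700 to 85185064), at 710.0 ± 51.2 in saline and 940.0 ± 151 in cocaine, and Per2 (chromosome 1, 91415982 to 91459324), at 1090.5 ± 173 in saline and 1953 ± 683 in cocaine, and Bhlhe41, at 1.28-fold of saline. The immediate early gene call was lost without saline replicate 2 (adjusted p = 0.0569 by limma camera) and without saline replicate 4 (0.109). The median of that list was 0.12 without saline replicate 2, 0.22 without saline replicate 1 and 0.07 without saline replicate 4. With the marker score held constant, the adjusted p was 0.0595 for immediate early genes and 0.169 for clock genes (limma camera). Without saline 1 and cocaine 1 it was 3.69e-05 for immediate early genes, with a median of 0.17, and 0.0247 for clock genes, with a median of 0.12.

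**Figure D3:**
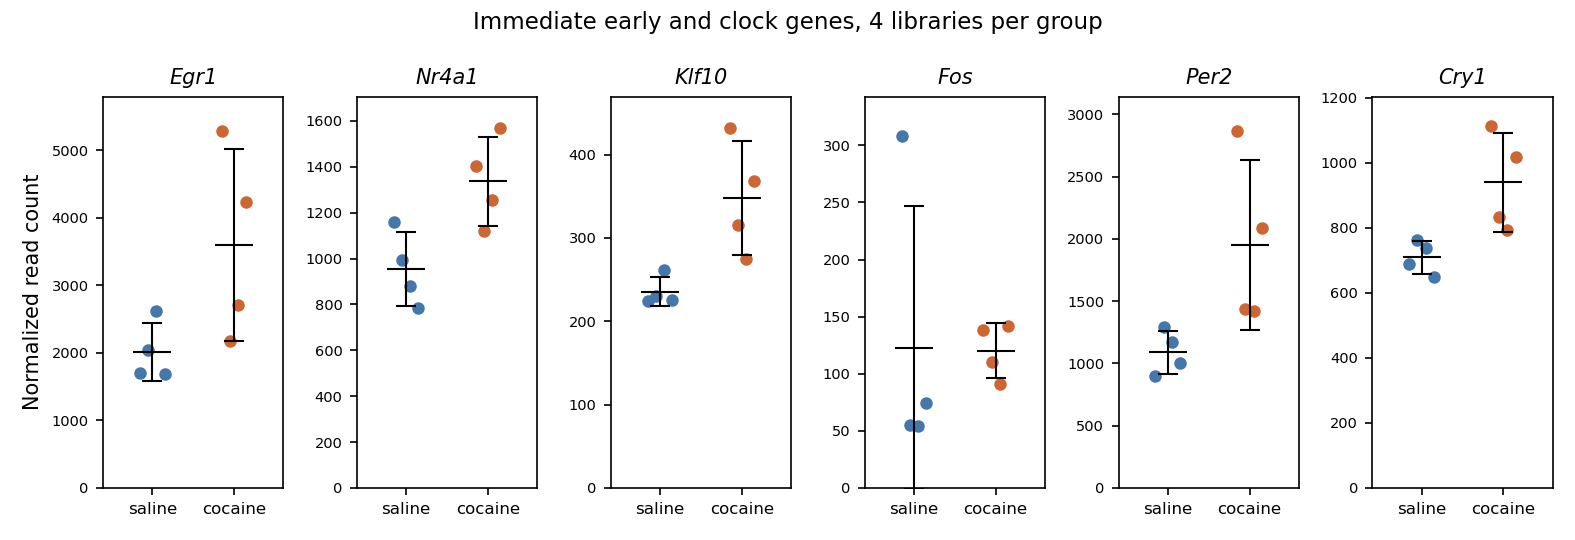
Normalized read counts of 4 immediate early genes and 2 clock genes in each library, on linear axes starting at 0, for saline (blue) and cocaine (orange); points are libraries, and the black bar and whiskers are the mean and SD of 4 libraries. The groups do not overlap for Klf10, Per2 and Cry1, overlap for Egr1 and Nr4a1, and Fos is highest in 1 saline library, at 308.

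Postsynaptic scaffold and adhesion genes had a median log2 difference of 0.18 over 32 members, with 24 positive and 4 higher at an unadjusted p below 0.05 (limma camera, adjusted p = 0.00483; adjusted p = 0.843 with an estimated correlation). The leading members were Lrrtm4, at 418 ± 47.3 in saline and 559 ± 52.8 in cocaine, and Lrrtm2, at 1713 ± 102 in saline and 2115 ± 263 in cocaine. Cytosolic ribosomal protein genes had a median of 0.07 over 79 members, 8 higher and 1 lower at an unadjusted p below 0.05 (limma camera, adjusted p = 0.0149; adjusted p = 0.843 with an estimated correlation). Rpl3 measured 974 ± 252 in saline and 1463 ± 238 in cocaine and Rps29 25.3 ± 3.05 in saline and 41.2 ± 10.2 in cocaine. Rpl3 overlaps Syngr1 on the other strand. Whether reads of ribosomal protein genes were shared with similar sequences was not tested. Mitochondrially encoded messenger RNAs had a median of 0.06 over 9 members, 2 of them at an unadjusted p below 0.05 (limma camera, adjusted p = 0.0184; adjusted p = 0.843 with an estimated correlation). The complex I subunit gene mt-Nd6 measured 16987 ± 2451 in saline and 21669 ± 1898 in cocaine. It overlaps mt-Nd5 on the other strand. The leading member mt-Co3 had 0 to 2.92 normalized counts in saline and 3.58, 6.87, 90.4 and 7.19 in cocaine. Its reads are uncertain, and whether they were shared with a near-identical nuclear copy was not tested. Chromatin modifier genes had a median of 0.06 over 66 members, 9 higher and 3 lower at an unadjusted p below 0.05 (limma camera, adjusted p = 0.0397; adjusted p = 0.843 with an estimated correlation). The histone methyltransferase gene Kmt2a measured 8749.6 ± 844 in saline and 10267 ± 645 in cocaine, and the histone demethylase gene Kdm6a measured 1009 ± 45.7 in saline and 1168 ± 101 in cocaine. Adjusted over the list alone, 0 members of these 4 lists passed.

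Several of these calls were lost in other fits. Without saline replicate 1, the adjusted p by limma camera was 0.0689 for the postsynaptic list and for mitochondrial messenger RNAs, 0.108 for ribosomal protein genes and 0.355 for chromatin genes. The chromatin call was also lost without cocaine replicate 1 (0.216) and without cocaine replicate 4 (0.0564), with a median of 0.06 in the latter. Changes of processing also ended it, with an adjusted p by limma camera of 0.0548 with the replicate block, 0.0663 with TMM factors, 0.0911 with quantile normalization, 0.201 with array quality weights, and 0.0565, 0.0567 and 0.0573 with pseudocounts of 0.5, 1 and 5. The mitochondrial call was lost without a low-value filter (0.101), at a minimum mean of 50 (0.0528), with quantile normalization (0.0618) and with array quality weights (0.0597), and the ribosomal protein call with array quality weights (0.275). The mitochondrial median was 0.12 with each of these pseudocounts, 0.11 with TMM factors and 0.10 with voom weights. Without saline replicate 1 the median was 0.08 for postsynaptic, 0.05 for ribosomal protein and 0.03 for chromatin genes, and without saline replicate 3 it was 0.30 for postsynaptic and 0.10 for chromatin genes. Without cocaine replicate 1 it was 0.08 for postsynaptic and 0.03 for chromatin genes, and without saline replicate 2 it was 0.13 for ribosomal protein genes. The chromatin median was 0.04 with quantile normalization, array quality weights and voom weights, and the ribosomal protein median 0.03 with array quality weights. With the marker score held constant, the adjusted p was 0.719 for postsynaptic, 0.414 for ribosomal protein, 0.232 for mitochondrial and 0.960 for chromatin genes by limma camera. Without saline 1 and cocaine 1 it was 0.274, 0.424, 0.194 and 0.912.

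**Figure D4:**
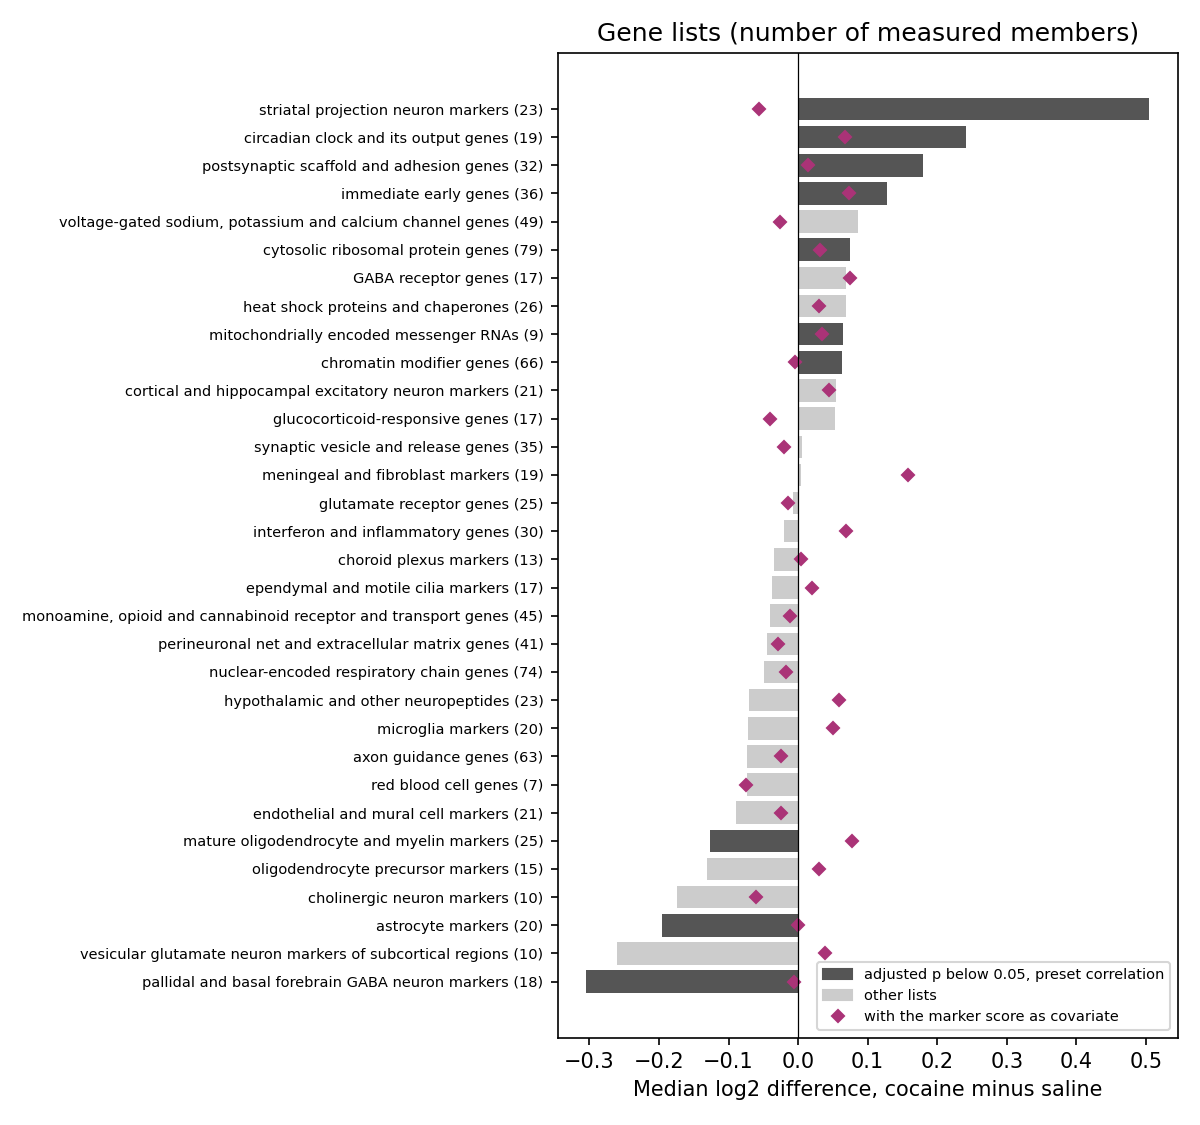
Median log2 difference, cocaine minus saline, of 32 gene lists; bars give the medians, dark where the camera adjusted p was below 0.05, and diamonds give the medians with the marker score as covariate. The median of the striatal list is 0.50 without the covariate and -0.06 with it.

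The other 22 lists did not pass, with camera adjusted p from 0.0600 to 0.954 in limma. Among neuron types, cholinergic markers had a median log2 difference of -0.17 (adjusted p = 0.0600), with Lhx8 at 0.75-fold and Ache at 0.82-fold of saline. Chat, the acetylcholine-synthesizing enzyme gene, measured 1462 ± 123 in saline and 1314 ± 264 in cocaine. Subcortical vesicular glutamate neuron markers had a median of -0.26 (adjusted p = 0.235), with Otp at 0.14-fold (0.35-fold without saline replicate 4) and Cbln4 at 1.14-fold, and Slc17a6, the vesicular glutamate transporter gene, measured 1131 ± 298 in saline and 728 ± 360.1 in cocaine. Cortical and hippocampal excitatory markers had a median of 0.06 (adjusted p = 0.931), with Mef2c at 1.37-fold and Nr4a2 at 0.66-fold. Neuropeptide genes had a median of -0.07 (adjusted p = 0.927), with Cartpt at 1.33-fold and the nociceptin precursor gene Pnoc at 0.45-fold.

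Leaving out cocaine replicate 2 brought 6 of these lists past an adjusted p of 0.05 in limma camera, namely endothelial and mural (adjusted p = 0.000216, median -0.20), extracellular matrix (0.0138, -0.10), cholinergic (0.016, -0.26), microglia (0.0305, -0.13), oligodendrocyte precursor (0.0356, -0.18) and axon guidance genes (0.0356, -0.12). Leaving out saline replicate 3 did so for oligodendrocyte precursor markers (0.0302) and voltage-gated channel genes (0.0349), saline replicate 2 for endothelial markers (0.0437), and saline replicate 4 (0.0353) and cocaine replicate 3 (0.0137) for cholinergic markers. Cholinergic markers also passed without a low-value filter (0.0312). Without cocaine replicate 1, the median was -0.04 for cholinergic markers (limma camera, adjusted p = 0.382), -0.10 for subcortical glutamate neuron markers (0.538), -0.05 for oligodendrocyte precursor markers (0.538), -0.01 for microglia markers (0.913) and 0.05 for channel genes (0.633). Without saline replicate 1 it was -0.06 for oligodendrocyte precursor markers (0.483), -0.02 for endothelial markers (0.435), 0.03 for channel genes (0.857) and -0.00261 for microglia markers (0.857), and without saline replicate 3 it was -0.23 for oligodendrocyte precursor markers. The heat shock median was 0.02 without cocaine replicate 1 and 0.04 without saline replicate 2. Leaving out 1 library moved the median by over 1.5 times in each of the 22 lists. The median changed sign in at least 1 of 16 planned fits for 10 of these 22 lists: cortical, neuropeptide, choroid plexus, ependymal, meningeal, red blood cell, glutamate receptor, GABA receptor, interferon and glucocorticoid-responsive genes.

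Among other cell types, oligodendrocyte precursor markers had a median of -0.13 (limma camera, adjusted p = 0.148), with Olig1 at 0.73-fold and Bmp4 at 0.75-fold. Microglia markers had a median of -0.07 (0.420), with P2ry12 at 1.12-fold and C1qa at 0.89-fold. Endothelial and mural markers had a median of -0.09 (0.121), with Vtn at 0.81-fold and Slc2a1 at 0.89-fold. Choroid plexus markers had a median of -0.03 (0.931), with F5 at 1.93-fold and Sostdc1 at 0.65-fold. F5 passed when adjusted over the list alone. Ependymal and cilia markers had a median of -0.04 and a camera direction upward (0.931). In that list Ccdc39, at 1.21-fold, passed when adjusted over the list alone, and Spag6l was at 1.23-fold. Meningeal and fibroblast markers had a median of 0.00386 (0.931), with the collagen genes Col6a1 at 1.55-fold and Col6a2 at 1.31-fold. The median was below 0 with pseudocounts on the recovered counts, with TMM factors and with voom weights. Red blood cell genes had a median of -0.07 (0.931), with Bpgm at 0.95-fold, and the median was 0.22 without saline replicate 3, 0.06 without cocaine replicate 1 and 0.21 with array quality weights.

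Among functional lists, glutamate receptor genes had a median of -0.01, a mean of 0.01 and an upward camera direction (limma camera, adjusted p = 0.931), with Grin2d at 0.68-fold and Gria2 at 1.25-fold. GABA receptor genes had a median of 0.07 (0.686), with Gabra2 at 1.27-fold and Gabbr2 at 0.84-fold. Monoamine, opioid and cannabinoid genes had a median of -0.04 (0.466), with the corticotropin-releasing hormone receptor gene Crhr1 at 0.76-fold and the cannabinoid receptor gene Cnr1 at 0.81-fold. Synaptic vesicle genes had a median of 0.0050 (0.889), with Cplx1 at 0.80-fold and Pclo at 1.16-fold. Voltage-gated channel genes had a median of 0.09 (0.416), with Hcn2, which passed when adjusted over the list alone, and Cacna2d1 at 1.20-fold. Axon guidance genes had a median of -0.07 (0.0754), with Sema7a passing when adjusted over the list alone and Sema4b at 0.88-fold. Extracellular matrix genes had a median of -0.04 (0.148), with Mmp15 at 0.74-fold and Hapln1 at 1.39-fold. Interferon and inflammatory genes had a median of -0.02 (0.927), with Isg15 at 1.36-fold and Vcam1 at 1.11-fold. Glucocorticoid-responsive genes had a median of 0.05, a mean of -0.01 and a downward camera direction (0.954), with Pdk4 at 1.20-fold and Mt2 at 1.41-fold. Heat shock and chaperone genes had a median of 0.07 (0.190), with Dnajb5 at 1.32-fold and Hspa1a at 0.77-fold. Nuclear-encoded respiratory chain genes had a median of -0.05 (0.190), with Ndufs7 at 0.89-fold and Ndufa8 at 0.87-fold. In the other lists of this kind, 0 members passed when adjusted over the list alone.

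The authors' deposited table listed 363 genes at an FDR below 0.05, 193 higher and 170 lower in cocaine, and 2533 genes at a p below 0.05. In the authors' deposited table the smallest p belonged to Tac2, the neurokinin B precursor gene, at a fold of 0.305. The authors' deposited table also gave Capn11 at 0.109, Nr4a3 at 2.69, Gal at 0.246, Irs4 at 0.375, Egr1 at 1.79 and Per2 at 1.79. Of the 363 genes, 359 were tested here, and all 359 had the same sign. Of these, 198 had an unadjusted limma p below 0.05 and 0 an adjusted p below 0.05, and the groups did not overlap for 44, or 12.3%. The authors' comparison was another test, in a table of 32787 genes. What makes the 2 numbers of calls differ was not tested. Tac2 measured 1200.2, 421, 123 and 2256 normalized counts in saline replicates 1 to 4 and 238, 570.1, 276 and 136 in cocaine. Gal and Irs4 were also highest in saline replicate 4, so their folds lean on that library. Gal measured 279.8 there and 32.2 to 184 in the other saline libraries, and Irs4 863 and 111 to 311.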

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

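The tests of tissue share, of chance and of 1 library in the first pattern, all tests in the second and the test of tissue share in the third were chosen only after the results were seen. A library stood apart when its gap to the nearest library of its group relative to the group's range exceeded Dixon's critical value for 4 values. This held for 18 of 246 groups of 4 values, where chance alone gives 12.3, about 1 in 20.

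Saline replicate 1 stood apart in 5 genes. Its normalized counts were 308 for Fos (54.6 to 74.4 in the other saline libraries), 1256.5 for Arc (704 to 717), 599 for Rpl3 (1064 to 1129), 64.5 for Spink8 (44.8 to 46.5) and 7490.0 for Kmt2a (9083 to 9276). Saline replicate 3 measured 24591 for Pcsk1n, 247 for Spag6l, 75.0 for Hspa1a and 1012 for P2ry12, and its mean log2 value of red blood cell genes was 9.41 against 8.44 to 8.60. Saline replicate 4 had 83.8 normalized counts of Otp, a hypothalamic transcription factor gene, against 6.82 to 19.4. In cocaine, replicate 3 had 90.4 of mt-Co3 and 346 of Pdk4, replicate 2 had 818 of Ccdc39 and a mean of 9.64 for endothelial and mural markers, and replicate 1 had 969.7 of Rb1, a mean of 6.43 for ependymal markers and 36171462 recovered reads.

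The first pattern is the higher striatal and lower pallidal markers in cocaine libraries. Within groups the list means moved in opposite directions over 8 libraries (Pearson r = -0.921, permutation p = 0.00174, the smallest that 576 orders can give; Spearman rho = -0.833, permutation p = 0.00347; r = -0.977 without saline 1 and cocaine 1), as a different share of striatal and pallidal tissue in the dissections would give. The correlation does not single out tissue share. As 1 principal component held 60.8% of the variance, other lists moved along with these, and astrocyte means also ran opposite to striatal means within groups. The difference in the score, 0.785, is one that chance differences between dissections may give (exact permutation p = 0.257). The striatal difference of 0.488 was 0.263 ± 0.362 (SE) without saline replicate 1, so the part of 1 library stays open. Of the genes called in the authors' deposited table outside both lists, 126 of 164 falls and 153 of 183 rises tracked the score within groups beyond 0.8 in the matching direction, against 29.1% of other genes beyond 0.8 either way. The called genes were not matched to these other genes for read count or spread, so the contrast does not by itself tie the calls to the score. An effect of cocaine on striatal or pallidal cells was not tested and also stays open.

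The second pattern is the lower Rn18s-rs5 and Mir6236 in cocaine, with a mean log2 difference of -1.14; both were picked after their values were seen, out of 4 features, of which Gm15564 measured 924 ± 190.3 in saline and 495 ± 69.9 in cocaine, and Gm23935, whose groups overlapped, 4951 ± 2027 in saline and 3020.2 ± 98.5 in cocaine. Tissue share as the whole cause is argued against by a difference of -1.16 ± 0.251 (SE) with the marker score held constant. Less ribosomal RNA of every kind is argued against by the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, which differed by 0.0702 ± 0.0191. Without saline replicate 3 the difference was -0.999 ± 0.171, more than 0.75 of its value but by less than its standard error, so by the bound set for this test the part of 1 library stays open. A lower carry-over of cytosolic ribosomal RNA alone, reads shared between copies of these sequences and an effect of cocaine were not tested.

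The third pattern is the higher immediate early and clock genes in cocaine, with a mean log2 difference of 0.228 over 55 genes. With the marker score held constant it was 0.117 ± 0.0784 (SE), and without cocaine replicate 1 it was 0.159 ± 0.0839, so neither tissue share nor that library can be excluded or shown as the cause. The hour at which tissue was taken is not in the labels, and an effect of cocaine was not tested.

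For genes past adjusted p 0.05 the count of 0 is reached by all 35 splits of the 8 libraries into 4 and 4, so the splits test nothing there, and the highest other count was 13. Chance cannot be excluded for the other counts. For unadjusted p below 0.05, 4 splits gave at least 2236 genes, and the highest other count was 5454. For gene lists, 15 splits gave at least 10, and the highest other was 16. The split with 13 and 5454 genes set saline 1, 2 and 4 and cocaine 2 against the others. This points to a structure of the libraries other than their group. These 4 libraries lay lowest on the first principal component of the log2 values, at -29.2, -4.31, -22.7 and -3.82. This component held 60.8% of the variance. Saline 1 lay lowest and cocaine 1 highest both on it and in the marker score. Cocaine 3 was next on the component, at -1.94, but lay below cocaine 2 in the score.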

How the results depend on the processing

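Added after seeing the data were the pseudocount of 1, voom weights, the marker score as covariate, alone and with an estimated correlation, the 2 libraries left out together and the permutation of list means; the other alternatives were planned. The count of 0 genes past adjusted p 0.05 held under all alternatives except that without a low-value filter, which gave 1 gene (Mir6236). The planned edgeR and DESeq2 fits were not run, as the deposited values per library are on a log2 scale. The recovered reads would have allowed them, so what a count model would call stays open. On the recovered reads, voom weights gave 0 genes. At unadjusted p below 0.05, the main count of 2236 ranged from 1075 to 4356 when single libraries were left out, and was 810 with the replicate number as a block and 708 without saline 1 and cocaine 1. The number of lists called, 10, ranged from 5 to 16 when single libraries were left out, was 5 without saline 1 and cocaine 1 and 3 with the marker score as covariate (0 with the score and an estimated correlation), and was 0 with an estimated correlation, 0 with fry and 0 by exact permutation of list means; the last shows nothing, since its smallest p is 0.0286 and 19 of 32 lists would have to reach it for any to pass. The drop to 0 with an estimated correlation in place of the preset one came with that change alone, as values and model stayed the same. What moved the other counts was not tested. With the block, 0 genes passed and 9 lists were called. Same-numbered libraries deviated in opposite directions from their group means (correlations across genes of -0.563, -0.265, -0.542 and -0.342). No saline library correlated best with its own number, so no pairing by number was seen. As 1 principal component held 60.8% of the variance, a smaller effect shared by number could be masked and is not excluded. The labels do not say what the numbers mark. With the marker score held constant, the medians of 14 of 32 lists changed sign, among them striatal (-0.0566), astrocyte (0.000108), myelin (0.0770), microglia (0.0507), chromatin (-0.00462) and interferon genes (0.0687); the last were also at 0.0639 without saline 1 and cocaine 1. The 10 called lists kept the sign of their median in 160 of 160 planned fits with the preset correlation, but not always the call: of 16 such fits, the chromatin list was called in 7, the mitochondrial list in 11, the immediate early, myelin and ribosomal protein lists in 14 each, the postsynaptic list in 15 and the striatal, pallidal, astrocyte and clock lists in 16 each. Of 1865 values of the 89 named genes, 7 had the other sign, for 6 genes that did not pass. Depth was 26163772 to 36171462 reads; counting error weighs more for genes near the minimum mean of 10 normalized counts, and its part in the spread was not tested.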

Other observations

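The tests in this part used the marker score, which was added after seeing the data; the permutation test was set before its result was seen. With the marker score held constant, 3 lists passed in limma's camera with the preset correlation, each with an adjusted p of 0.0248, and with an estimated correlation in the same fit the adjusted p was 0.834 for each. Interferon and inflammatory genes had a median log2 difference of 0.07 with the score and -0.02 without it, microglia markers 0.05 and -0.07, and meningeal and fibroblast markers 0.16 and 0.00386. Without saline 1 and cocaine 1, the adjusted p by limma camera was 0.0285 for interferon, 0.218 for microglia and 0.000215 for meningeal genes. Ifit3, an interferon-induced gene, had a log2 difference of 0.53 ± 0.08 (SE, limma adjusted p = 0.0561) in the fit with the score and of 0.23 ± 0.18 without the score. Nr1d1, a clock repressor gene, had a log2 difference of -0.37 ± 0.07 in the fit with the score and did not pass (limma adjusted p = 0.224). In that fit the median of the clock list was 0.07. Without the score the log2 difference of Nr1d1 was -0.21 ± 0.11 (SE). A candidate explanation for the 3 lists is chance between libraries. The mean of their 69 genes, with the score removed, was higher by 0.105 ± 0.0656 (SE), and a permutation of the group labels gave p = 0.0571. This p is not exact, since the score was removed with a slope fitted alongside the real groups. The 3 lists were also picked because they passed in the same fit, so the test cannot settle the question.

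The genes in the rest of this part were named after their values were seen. The peptide precursor gene Tac2 measured 2256 normalized counts in saline replicate 4 and 123 in saline replicate 3, and Gal 279.8 and 32.2. The receptor substrate gene Irs4 measured 863 in saline replicate 4 and 111 in saline replicate 3. In the cocaine libraries Tac2 measured 136 to 570.1.

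Capn11, a calpain gene, measured 238, 138, 116 and 28.3 in saline and 9.85, 8.83, 25.5 and 12.3 in cocaine, with no overlap between groups and a limma adjusted p of 0.418. The ribosomal protein gene Rpl31 measured 902 in saline replicate 3 and 115 to 199.7 in the other libraries. The choroid plexus gene Ttr measured 33.1 in saline replicate 3 and 349 in saline replicate 1.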
